A study of Rattus norvegicus with 10 samples.

How the data were processed

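Reduced representation bisulfite sequencing libraries were made by the submitters from DNA of the hypothalamic arcuate nucleus of 10 Wistar rat offspring, with a Zymo-Seq kit, per the labels' protocols. The label of chow-fed fathers was carried by 5 samples and 5 carried that of high-fat-fed fathers, and all offspring received a high-fat diet from postnatal day 35 to 70. The labels call these separate samples and do not state litter, sire or sex; whether littermates are among them is unknown. The offspring were treated as separate animals, so p-values measure the spread between these samples.

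One processed table was analysed. Per the submitters' processing notes, reads were handled with Trim Galore, Bismark and Bowtie, without versions. Regions were called with metilene on the 2 groups, per the file name and headers. The genome build, the coverage filter, the conversion rate and the metilene settings are not given in the sources used here, and coordinates are printed as the file gives them, without knowledge of whether its start positions count from 0 or 1. For each of 8957 regions the deposited values were the methylation fraction averaged per animal, the group mean fractions, their difference, a q-value, and Mann-Whitney and 2-dimensional Kolmogorov-Smirnov p-values, all as the authors wrote them. The number of CpGs per region and the distance to the nearest start site, with Ensembl gene and transcript identifiers, were also the authors'. Tests on the file showed at least 10 and at most 58 CpGs per region and a median length of 66.0 bases. No absolute group difference deposited by the authors was under 1 percentage point. The deposited q was 1 for 8770 regions. Of 89570 averages, 127 were missing, 82 of them in 1 paternal chow column. Fractions were multiplied to percent. The authors' group means differed from the mean of the animals' levels by 0.166 points on average, and the direction differed at 12 regions; levels and directions are from the animals' means unless the authors' deposited table is named.

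Neither counts nor coverage came with the levels, so depth is unknown per sample and per region, counts could not be tested, and no interval for counting error is given. Without depth the precision of a single level cannot be stated, and the spread between animals is the only error given. Columns carried animal names that show the group but match no sample title, so they were used as 5 replicates per group without replicate numbers; no other column of levels was present. Of 5565 distinct gene names, 4862 matched a symbol of the reference gene table and 113 a synonym. A region's gene is the one the file names, by nearest start site, and 37 regions had none.

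Levels per region were compared with limma (version 3.58.1, R 4.3.3; empirical Bayes with a mean-variance trend) and Benjamini-Hochberg adjustment at 0.05, as fixed before the data were examined for a file with levels and no counts. Mean and median levels per animal were compared with two-sided exact permutation tests over 252 arrangements. Directions of classes, chromosomes and lists were compared with two-sided Fisher's exact tests, adjusted within each family, and shares were given Clopper-Pearson intervals at 95%, with SciPy 1.17.1, pandas 2.3.3 and Python 3.11.15; figures were drawn with matplotlib 3.10.9. The Fisher tests and the intervals treat regions as independent, although all regions come from the same animals. The 18 gene lists were fixed before the data were examined, with markers of other cell types among them. The limma step was tested on simulated data with the levels and spread of the 8957 regions for the same comparison of 5 against 5 animals. Of 50 changed regions per size, most at low levels, it called 2% at a difference of 2 points, 58% at 5, 92% at 10 and 98% at 20, with 1 false call. A changed region kept the spread of its unchanged level. The shares called therefore do not give the power for real differences of these sizes, many of which lie at more variable intermediate levels.

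Regions were named by a rule fixed before the data were examined: with limma calls, the 10 higher and 10 lower with the largest difference and no overlap, members of the feeding lists and up to 3 of each other list, and the 3 genes with most calls; and the 5 regions with the smallest deposited q. Since limma gave no call, only the last part named regions. The same rule was then applied to regions with a deposited q below 0.05, and the 2 regions with the smallest unadjusted p of each list were added as examples; both choices were made after the values had been seen. Alternatives were a logit scale with an offset of 0.01, stricter thresholds, minimum differences and CpG numbers, adjustment over the other deposited p-values, autosomes only, leaving out each animal, and, chosen after the data were seen, robust and untrended variance, an exact permutation test per region, averaging of columns with the same leading number, and leaving out 2 columns together. A region that the rule named is not reported here. Metilene itself was not rerun, since CpG-level values were not analysed here.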

Results

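DNA methylation was measured in the arcuate nucleus, the part of the hypothalamus that senses circulating metabolic signals and governs feeding, in 10 rat offspring. The comparison asked whether the diet of the father left a difference in the offspring. The fathers were Wistar rats kept on a high-fat diet or on chow, and the mothers were fed chow. Each paternal diet was represented by 5 offspring. All 10 offspring ate chow until postnatal day 35 and a high-fat diet from then until tissue was taken on postnatal day 70, so paternal diet was the only labelled difference between the groups. Reduced representation bisulfite sequencing, which reads the methylation of CpG-rich restriction fragments, gave an average methylation level per animal for each of 8957 regions. The regions had been selected by the authors on these same animals, so no test on them is independent evidence of a difference. Each held at least 10 CpGs and a difference of at least 1 percentage point between the authors' deposited group means. Between the animals' means the difference was smaller at some regions, such as 0.104 points at an intron of Ephb1. The sequencing depth behind each level is unknown, and no interval that needs it is given.

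Across these regions the methylation level was higher in offspring of high-fat-fed fathers. The mean level per animal was 7.23% ± 0.672 (SD, n = 5) in the paternal high-fat group and 6.13% ± 0.295 (SD, n = 5) in the paternal chow group. The difference of 1.10 points exceeded the spread between animals, and every paternal high-fat animal (6.48% to 8.24%) lay above every paternal chow animal (5.72% to 6.46%; two-sided exact permutation test, p = 0.00794, the smallest that 5 against 5 animals can give). The median level per animal was 2.73% ± 0.628 (SD, n = 5) against 1.70% ± 0.194 (SD, n = 5), again with separate groups (exact permutation p = 0.00794). Because the regions were picked for a difference between these groups, this contrast describes the selected regions and not the genome.

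**Figure D1:**
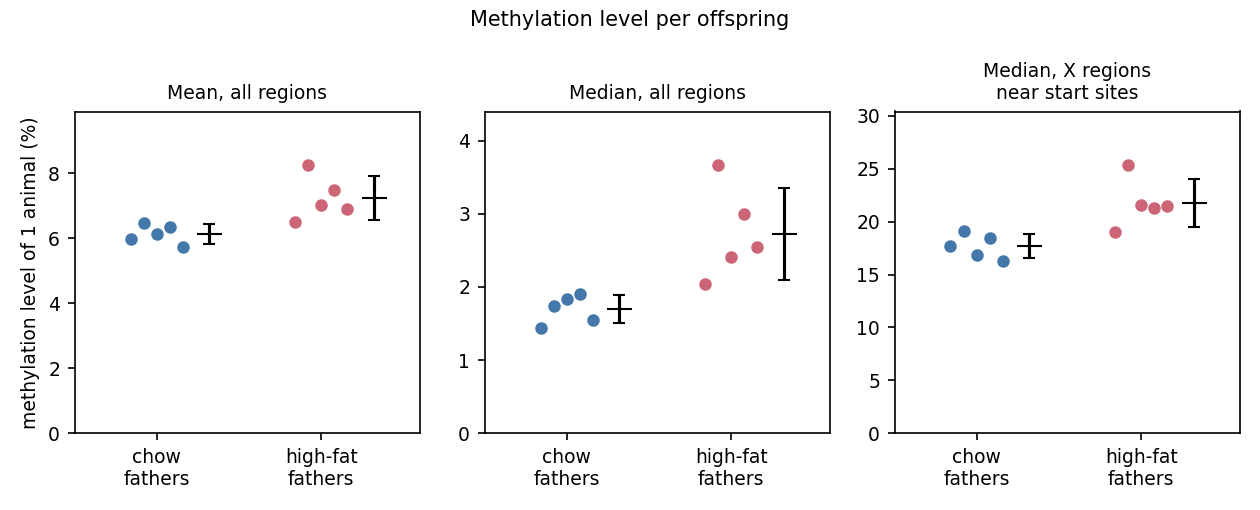
Methylation level (%, vertical axis) of each offspring, by paternal diet (horizontal axis): the mean over all 8957 regions, the median over them, and the median over 135 X-linked regions within 1000 bases of a transcription start site. Points are animals, and the black marks beside them are the group mean ± SD (n = 5). In the mean, the 5 paternal high-fat animals span 6.48% to 8.24% and lie above the 5 paternal chow animals.

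Of the 8957 regions, 6357 had a higher mean level in paternal high-fat offspring and 2600 a lower one, so 71.0% were higher (95% Clopper-Pearson interval 70.02% to 71.91%, which treats regions as independent). The differences were small: their median absolute size was 1.74 points, 8367 were under 5 points, and 60 reached 10 points, of which 55 were higher. The majority was present at low methylation, with 70.1% of 7260 regions at up to 5% methylation higher, and at intermediate methylation, with 80.1% of 579 regions between 20% and 80% higher (95% Clopper-Pearson interval 76.7% to 83.3%). Among 131 regions above 80% methylation, 56.5% were higher, with an interval of 47.6% to 65.1%.

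No single region passed the test across animals. With limma on the deposited levels, 0 of 8957 regions had an adjusted p below 0.05, and the smallest adjusted p was 0.235. An unadjusted p below 0.05 was found for 1875 regions, 1470 higher and 405 lower in paternal high-fat offspring, where 447.85 would come by chance in regions not selected for a difference. An exact permutation test per region had 2205 of 8838 regions with complete values at an unadjusted p below 0.05. Its adjusted count of 0 adds little, since with a smallest possible p of 0.00794 at least 1403 regions must pass together for any to pass, and 456 were at that p. The groups did not overlap in any animal at 461 regions, 352 of them higher; unselected regions would give 0.794%, or 71.1 regions. In the authors' deposited table, by contrast, 76 regions had a q below 0.05, 66 with a higher and 10 with a lower mean in paternal high-fat offspring. Of these 76, 63 had an unadjusted limma p below 0.05 and 30 had groups that did not overlap.

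The smallest q in the authors' deposited table (2.46e-07) belonged to Adamts2 (ENSRNOG00000061484), which encodes a protease that processes procollagen. Its region lay at the promoter on chromosome 10, 36098316 to 36098388, and held 21 CpGs. Its level was 5.15% ± 2.41 (SD, n = 5) in paternal high-fat and 1.39% ± 1.03 (SD, n = 5) in paternal chow offspring, and 4 of the 5 Adamts2 regions were higher. Another of the 5 smallest q, 3.97e-06 in the authors' deposited table, was named for Galp (ENSRNOG00000022129), which encodes galanin-like peptide, a feeding-related neuropeptide of the arcuate nucleus. This region of 13 CpGs lay on chromosome 1, 71383364 to 71383506, in an annotated exon at −9830 bases from the Galp start site, so the file ties it to Galp by distance. Its level was 45.6% ± 6.54 (SD, n = 5) against 28.7% ± 7.50 (SD, n = 5), and the lowest paternal high-fat animal (36.6%) lay above the highest paternal chow animal (34.6%); paternal chow animal 6HFBB, at 15.6%, lay far below its group. The other Galp region, in the same exon at 71383205 to 71383253, lay the other way, with 27.7% ± 5.82 against 37.3% ± 13.9 (SD, n = 5 each). A further 2 of them were intergenic regions on chromosome 7, nearest to an annotated 5_8S_rRNA copy (ENSRNOG00000056796), a ribosomal RNA gene. They lay 39767 and 42374 bases from its start site, so the file ties them to it by distance. The one at 99524804 to 99525693 averaged 73.0% ± 6.49 (SD, n = 5) against 57.7% ± 18.1 (SD, n = 5), and its difference of 15.3 points was 9.996 points without the paternal chow animal 2HFB. The one at 99522547 to 99522737 averaged 8.27% ± 2.50 (SD, n = 5) against 3.22% ± 1.72 (SD, n = 5). For each of these 4 regions the limma adjusted p was 0.235.

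Other regions with q below 0.05 in the authors' deposited table and no overlap between groups included an intron of Col16a1, a collagen gene (chromosome 5, 148286680 to 148286776, intron 42 of 70). It had the largest difference of them, with 67.0% ± 7.06 (SD, n = 5) in paternal high-fat and 45.5% ± 5.14 (SD, n = 5) in paternal chow offspring, of which 6HFB stood highest at 54.6%. An intron of Sh3rf3 (chromosome 20, 28671542 to 28671615, intron 6 of 8) averaged 17.8% ± 7.32 against 6.65% ± 1.46 (SD, n = 5 each). An exon of Ccdc102a (chromosome 19, 10523340 to 10523394, exon 2 of 9) averaged 12.9% ± 2.91 against 5.48% ± 1.69 (SD, n = 5 each), and 4 of the 5 Ccdc102a regions were higher. Promoter regions near-unmethylated in paternal chow offspring were among them: that of Fancg, a Fanconi anaemia DNA repair gene (chromosome 5, 58455927 to 58455996), averaged 5.60% ± 4.37 against 0.367% ± 0.462 (SD, n = 5 each). Ndufa9, which encodes a subunit of mitochondrial complex I (chromosome 4, 159399559 to 159399603), averaged 5.53% ± 2.65 (SD, n = 4) against 0.448% ± 0.632 (SD, n = 5).

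Of the 10 regions lower in paternal high-fat offspring with q below 0.05 in the authors' deposited table, 3 had groups that did not overlap. The first intron of Maff, a small bZIP transcription factor gene, averaged 0.544% ± 0.343 (SD, n = 5) in paternal high-fat and 4.35% ± 2.45 (SD, n = 5) in paternal chow offspring (chromosome 7, 120580733 to 120581002). The first exon of Ntrk2 (ENSRNOG00000018839), which encodes TrkB, the receptor of brain-derived neurotrophic factor, averaged 1.18% ± 0.563 against 4.26% ± 3.35 (SD, n = 5 each; chromosome 17, 6244354 to 6244428). The promoter of Arhgef11 averaged 0.757% ± 0.760 against 4.60% ± 4.82 (SD, n = 5 each; chromosome 2, 186979861 to 186979931). Paternal chow animal 4HFB was the highest of its group at both Ntrk2 (10.2%) and Arhgef11 (13.2%). Without it the difference went from −3.09 to −1.59 points at Ntrk2 and from −3.84 to −1.69 points at Arhgef11.

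**Figure D2:**
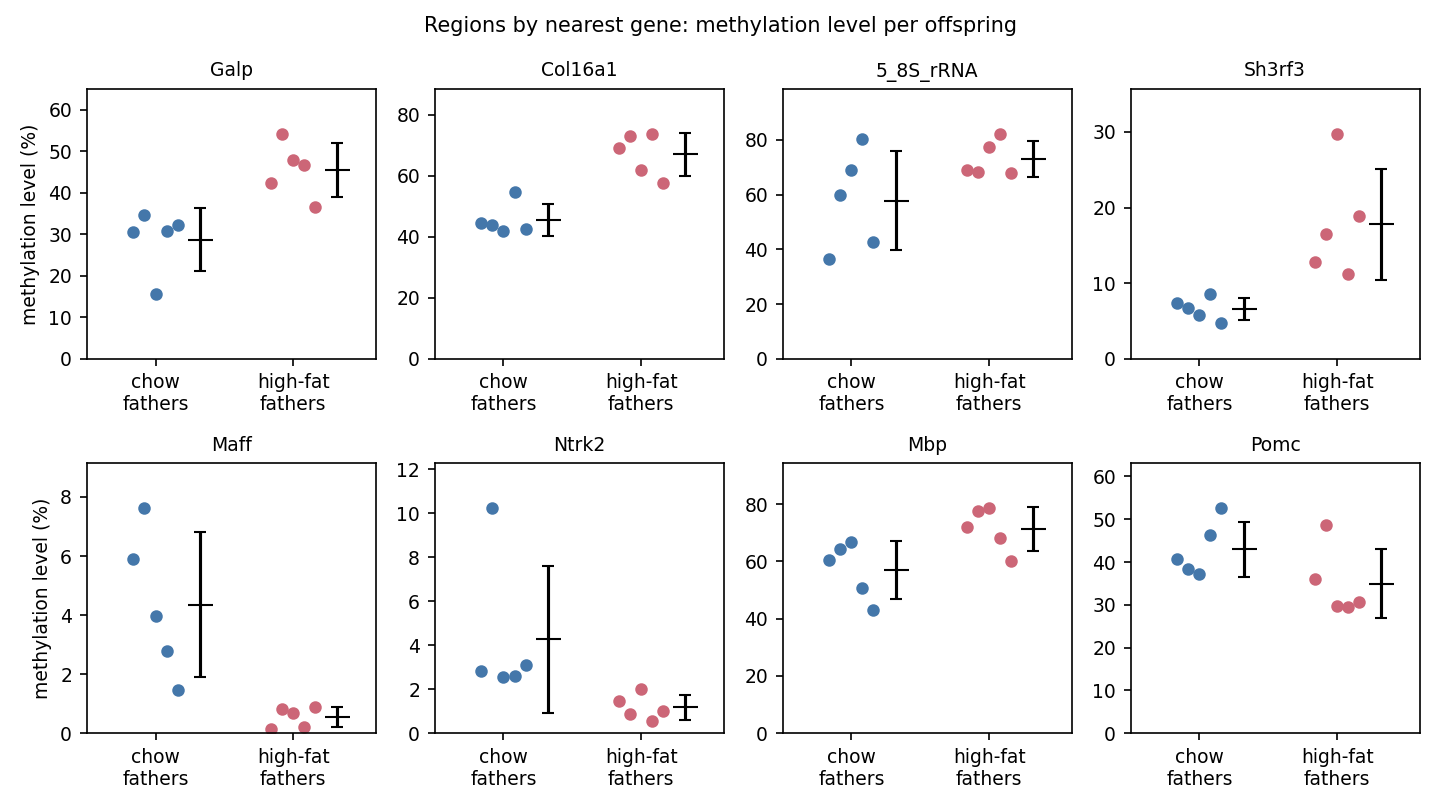
Methylation level (%, vertical axes starting at 0 and scaled per panel) of each offspring at 8 regions named by their nearest gene, by paternal diet (horizontal axis). Points are animals and black marks the group mean ± SD (n = 5). The groups do not overlap at Galp, Col16a1, Sh3rf3, Maff and Ntrk2, and they overlap at 5_8S_rRNA, Mbp and Pomc; none of the 8 regions had a limma adjusted p below 0.05.

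Of the 25 appetite neuropeptide genes listed before the data were examined, 5 had a region, 2 higher (Sst and Adcyap1) and 3 lower (Pomc, Trh and Cck) in paternal high-fat offspring. Galp is not on that list, so its 2 regions, 1 higher and 1 lower, are not counted here. The region at −15506 bases from the start of Pomc, which encodes the precursor of the satiety peptide alpha-MSH, averaged 34.9% ± 8.08 (SD, n = 5) against 43.0% ± 6.41 (SD, n = 5), and its difference did not pass (limma adjusted p = 0.238). Of 29 feeding receptor and related genes, 8 had 16 regions, 12 higher and 4 lower. They included the Ntrk2 region and a region in the first intron of Crhr1, the receptor of corticotropin-releasing hormone, which averaged 5.47% ± 4.29 against 0.915% ± 0.739 (SD, n = 5 each). The Crhr1 difference of 4.56 points was 2.75 points without paternal high-fat animal 24HFB. Of 36 leptin and insulin signalling genes, 20 had 44 regions, 30 higher and 14 lower. Ptpn2, which encodes a phosphatase that restrains insulin and leptin signalling, had regions in both directions. The region in its first intron (chromosome 18, 63487875 to 63487908) averaged 2.70% ± 1.61 against 0.559% ± 0.589 (SD, n = 5 each). The region at its promoter (63488062 to 63488119) averaged 0.176% ± 0.242 against 2.11% ± 3.13 (SD), with a wide spread in paternal chow offspring. Both regions of Pdpk1, a kinase of the insulin pathway, were lower, the one in its first intron at 0.491% ± 0.414 against 1.72% ± 0.612 (SD, n = 5 each). No direction test separated these lists from the other regions (Fisher's exact test, adjusted p = 0.557 for the neuropeptides and 1 for both others).

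Imprinted genes, which are expressed from the allele of a single parent, had the list direction with the smallest p: 28 of 31 regions (90.3%) at 12 genes were higher in paternal high-fat offspring (Fisher's exact test, p = 0.0162, adjusted over the 18 lists p = 0.292). The list therefore did not pass. Zrsr1 averaged 36.4% ± 7.63 against 24.4% ± 3.60 at its promoter (SD, n = 5 each; chromosome 14, 107749095 to 107749491), while another Zrsr1 region, in an intron, differed by −11.1 points. Phlda2, a growth-restraining placental gene, averaged 4.60% ± 1.28 against 1.21% ± 0.461 at its promoter without overlap (SD, n = 5 each; chromosome 1, 216703523 to 216703605), with animal 22HFR at 6.87% and the other paternal high-fat animals at 3.83% to 4.21%. With each gene counted once, 11 of 12 imprinted genes were higher (Fisher's exact test, p = 0.201, adjusted p = 0.818).

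Lists of neuronal signalling genes are set beside the 71.0% of all regions that were higher in paternal high-fat offspring. Dopamine, opioid and endocannabinoid genes had 11 of 12 regions higher. Among them was an intergenic region at −8803 bases from the start of Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32. That region averaged 6.15% ± 1.54 against 2.94% ± 1.08 (SD, n = 5 each). An exon of the receptor gene Drd4 averaged 3.60% ± 2.02 against 0.903% ± 0.410 (SD, n = 5 each). GABA and glutamate genes had 16 of 25 higher (64%), with an intron of Grin2c, 3 of whose 5 regions were higher, at 12.8% ± 3.65 against 7.55% ± 2.39, and Grik2 at 1.38% ± 0.902 against 3.94% ± 1.54 (SD, n = 5 each). Serotonin, noradrenaline and stress genes had 15 of 19 higher, including 3 of the 4 promoter regions of the adrenoceptor gene Adra2c. The Adra2c region at 80732769 to 80732821 on chromosome 14 averaged 2.75% ± 1.49 against 0.442% ± 0.151 (SD, n = 5 each). The adjacent one at 80732835 to 80732933 lay the other way, at 0.857% ± 0.787 against 2.68% ± 2.99 (SD), a difference within the spread of the paternal chow animals. Ion channel genes, chiefly of calcium and potassium channels, had 45 of 55 higher; the Kcnma1 promoter averaged 5.05% ± 4.63 against 0.0397% ± 0.0887 (SD, n = 5 each), and its difference of 5.01 points was 3.14 points without paternal high-fat animal 22HFR. Synaptic adhesion and axon guidance genes had 41 of 64 higher (64.1%), with the X-linked neuroligin gene Nlgn3 at 17.6% ± 5.44 against 9.55% ± 3.20 (SD, n = 5 each); animal 22HFR was at 27.2% and the other paternal high-fat animals at 14.1% to 17.1%. Clustered protocadherins had 1 of 3 higher. The shares of these last 2 lists and of the GABA and glutamate genes lay below that of all regions. None of these lists passed the direction test (adjusted p 0.557 to 1).

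Against the same 71.0%, hypothalamic transcription factor genes had 45 of 62 regions higher (72.6%), with Sox2 at 5.58% ± 2.02 against 1.65% ± 1.10, while a region in the last exon of Fezf1 averaged 15.7% ± 4.14 against 25.9% ± 3.46 (SD, n = 5 each). Regulators of DNA methylation and chromatin had 33 of 42 higher, including the promoter of Ezh2, the catalytic subunit of a repressive histone methyltransferase complex, at 2.28% ± 1.40 against 0.456% ± 0.346 (SD, n = 5 each). Lipid and energy genes had 27 of 33 higher, with the promoter of the adipogenic nuclear receptor gene Pparg at 3.82% ± 1.35 against 1.38% ± 0.438 (SD, n = 5 each). A region in an annotated intron at −12008 bases from the Ppard start site averaged 2.16% ± 0.880 against 4.56% ± 1.26 (SD, n = 5 each). The file ties this region to Ppard by distance, and the intron may belong to another gene. The other 2 regions named for Ppard were higher, by 2.60 points at 7803961 and by 2.21 points at 7806478, where the lower region ends. Circadian genes had 18 of 21 higher, with Bhlhe41 at 2.22% ± 1.08 against 0.367% ± 0.287 (SD, n = 5 each). The adjusted p of direction was 0.623 for the regulators of DNA methylation and chromatin, 0.557 for the lipid and circadian lists and 1 for the transcription factors.

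Markers of other cell types that a dissection can hold were listed too. Oligodendrocyte lineage genes had 6 of 9 higher, among them an exonic region of Mbp, the myelin basic protein gene, at 71.3% ± 7.51 against 57.0% ± 9.98 (SD, n = 5 each), with overlapping groups. Astrocyte and tanycyte genes had 5 of 7 higher, inflammation and microglia genes 4 of 6, and blood, vessel and pituitary genes 4 of 6. Each of these 4 lists had an adjusted p of direction of 1. Over all 18 lists, 231 of 648 genes had a region, and limma gave 0 calls in each list both over all regions and adjusted over the list alone. In the authors' deposited table, regions of list members with a q below 0.05 included those named for Ntrk2 and for Dlgap4, a postsynaptic scaffold gene. The Dlgap4 region was intergenic, at −51044 bases from its start site, so the file ties it to Dlgap4 by distance. It averaged 2.76% ± 1.62 against 0.745% ± 0.485 (SD, n = 5 each; chromosome 3, 152701017 to 152701076). A neighbouring intergenic region at 152700947 to 152700966, at −51134 bases, lay the other way, with 0.050% ± 0.112 against 1.15% ± 0.731 (SD, n = 5 each). Another intergenic region named for Dlgap4, at 152701108, was higher by 1.01 points.

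**Figure D3:**
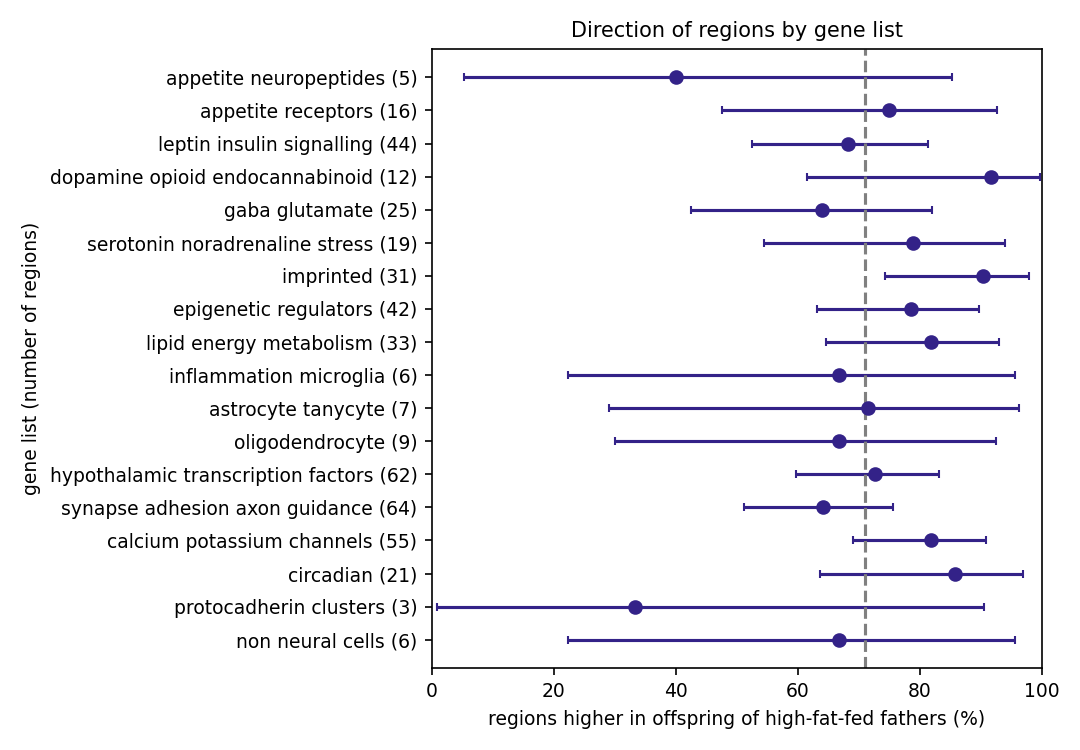
Share of regions with a higher mean level in offspring of high-fat-fed fathers (%, horizontal axis) for each of 18 gene lists, with the number of regions in brackets (vertical axis). Points are shares, bars are 95% Clopper-Pearson intervals that treat regions as independent, and the dashed line is the share of all 8957 regions, 71.0%. Every interval but that of the imprinted list holds the dashed line, and no list passed the direction test after adjustment.

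By the file's own annotation, 3430 regions lay at promoters, 1807 in exons, 1704 in introns, 1772 between genes and 236 at transcription termination sites, and 5950 (66.4%) lay within 1000 bases of a start site. Between 70.6% and 71.9% of regions were higher in each class (Fisher's exact test, adjusted p = 1 in all 5). By chromosome, X passed the direction test: 149 of 184 X-linked regions (81.0%) were higher against 70.8% of the others (Fisher's exact test, p = 0.00229, adjusted over 21 chromosomes p = 0.0482). This test counts regions of the same 10 animals as independent. Some X-linked regions lay close together, such as 11 at LOC690348 between 156227142 and 156231726, so the p may be too small. X-linked regions had a median level of 20.9%, so they were also compared with autosomal regions of intermediate level, a test chosen after the values were seen. Between 20% and 80% methylation, 83.9% of 93 X-linked and 79.4% of 485 autosomal regions were higher, a difference that did not pass (Fisher's exact test, p = 0.395). The median X-linked level near start sites was 21.7% ± 2.28 (SD, n = 5) in paternal high-fat and 17.7% ± 1.14 (SD, n = 5) in paternal chow offspring (two-sided exact permutation p = 0.0159).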

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

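All tests of explanations in this part were chosen after the result they bear on had been seen. A value was listed when it stood far from the other 4 animals of its group by Dixon's criterion (0.71 for 5 values). Of 122 groups tested, 17 met it. The criterion is met by about 1 in 20 groups of normally distributed values, but many levels here lay at or near 0. Where the other 4 animals were all at 0, any higher value met it, as at Kcnma1. The 17 therefore cannot be set against chance.

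Paternal chow animal 4HFB differed from its group in 3 summary values: it had 82 missing averages against 1 to 9 in the others, held the highest level of the 10 animals in 13.7% of regions against 2.45% to 5.56%, and had a median of 4.86% against 2.25% to 2.98% over regions lower in paternal high-fat offspring. It also stood apart at Ntrk2 (10.2%, others 2.55% to 3.09%) and Arhgef11 (13.2%, others 2.26% to 2.53%). Low depth of that library is a candidate explanation: its 82 missing averages were the most of the 10, as were its averages at exactly 0 (20.5%). Paternal high-fat animal 22HFR held the highest level in 27.2% of regions. Its 2 missing averages lay near the median of 3.0, and 5.84% of its averages were at exactly 0, so neither value set it apart as for 4HFB. A thinly covered average is not missing, so these values cannot decide on low depth there. Depth itself is unknown, and a biological difference of these animals was not tested.

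Animal 22HFR stood above its group at Nlgn3 (27.2%, others 14.1% to 17.1%), Phlda2 (6.87%, others 3.83% to 4.21%), Grik2 (2.95%, others 0.738% to 1.27%) and the Dlgap4 region at 152700947 (0.250%, others listed at 0). Animal 24HFB stood above its group at RGD1560108 (25.0%, others 16.9% to 17.4%). Among paternal chow animals, 6HFBB was high at Cacna1h (5.30%, others 0 to 0.777%) and at the Adra2c region at 80732769 (0.711%, others 0.366% to 0.385%), and low at Galp (15.6%, others 30.6% to 34.6%). Animal 6HFB was high at Col16a1 (54.6%, others 42.0% to 44.4%), Kcnma1 (0.198%, others listed at 0) and the Adra2c region at 80732446 (0.364%, others listed at 0). Animal 2HFB was low at the 5S_rRNA region (82.5%, others 91.1% to 93.1%).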

How the results depend on the processing

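Alternatives chosen after the data were seen are marked as added. Limma gave 0 regions at adjusted p below 0.05 under each setting run: the smallest adjusted p was 0.0947 on the logit scale, 0.235 with robust variance (added), 0.0833 without the trend (added), 0.242 with same-numbered columns averaged (added) and 0.215 to 0.293 with each animal left out. The exact permutation test (added) also gave 0, with a smallest adjusted p of 0.154, but its few arrangements nearly fix that count. Regions at unadjusted p below 0.05 numbered 1392 (without 2HFB) to 2072 (without 22HFB) with an animal left out and 2294 on the logit scale. The 76 regions of the authors' deposited table fell to 45 at q below 0.01, to 31 with at least 20 CpGs, to 7 with an absolute difference of at least 10 points and to 1 with at least 20, each by the alternative's own construction. Adjustment over the deposited Mann-Whitney p gave 5224 regions, 3859 higher and 1365 lower in paternal high-fat offspring (73.9% higher). Over the Kolmogorov-Smirnov p it gave 3026, 2338 higher and 688 lower (77.3%). The 86.8% higher among the 76 regions was not reached with either, and the cause was not tested. These counts and the 76 are not like-for-like, since both adjustments were Benjamini-Hochberg adjustments over the selected regions only. At named regions with q below 1, the deposited q was instead a near-constant multiple of the deposited Kolmogorov-Smirnov p, larger than the number of regions. The 2 kinds of adjustment therefore differ in method as well. The q and that p were 2.46e-07 and 1.52e-12 at Adamts2, and 0.709 and 4.39e-06 at Phlda2. The share of regions higher in paternal high-fat offspring was 69.8% (without 22HFR) to 72.3% (without 4HFB) with an animal left out, and 86.8% among regions with a deposited q below 0.05 (added). The difference of mean level was 0.849 (without 22HFR) to 1.29 points (without 22HFB) and stayed past the threshold throughout, also without 22HFR and 4HFB together (added; 0.933 points, exact permutation p = 0.0286). No list passed with only regions within a gene or 5000 bases of its start, or with genes as units. Of 583 values of the 53 named regions under alternatives, 0 reversed. Where the groups did not overlap, leaving out or averaging animals cannot reverse a difference, so this count was partly fixed in advance. Beyond those given with their genes in the report, leaving out 1 animal moved Mal from 3.52 to 2.27 points (without 22HFB) and Sst from 1.31 to 0.843 (without 28HFB) by over 1.5 times.

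No paired analysis was possible because the columns carry no replicate numbers. Coverage minimums of 5 and 20 reads were not run, since coverage was not analysed here. Unknown depth limits every level, and the selection of regions on all 10 animals holds in the settings that leave an animal out too.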

Other observations

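All tests in this part were chosen after the result they bear on had been seen. Some loci held many regions. Gnas, an imprinted gene that encodes a stimulatory G protein subunit used by melanocortin receptors among others, had 11 regions between 172374816 and 172421202 on chromosome 3, and all 11 were higher in paternal high-fat offspring, by 2.28 to 8.51 points. Their mean was 26.8% ± 4.56 (SD, n = 5) against 21.7% ± 3.08 (SD, n = 5), a difference of 5.10 points with an exact permutation p of 0.0714 (adjusted over 19 gene names with at least 8 regions, p = 0.151), so it did not pass. None of the 11 had an unadjusted limma p below 0.05, and the smallest q among them in the authors' deposited table was 0.274. Without Gnas, 17 of 20 imprinted regions were higher (Fisher's exact test, p = 0.220). Between 20% and 80% methylation, 12 of 13 imprinted regions and 79.8% of other regions were higher (Fisher's exact test, p = 0.481).

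Developmental transcription factor genes were also among those with at least 8 regions. Tbx2 had 8 of 9 regions higher, with a mean of 8.79% ± 0.836 against 7.08% ± 0.714 (SD, n = 5 each; exact permutation p = 0.0159, adjusted p = 0.0754). Lhx5 had 10 of 11 higher, with 8.89% ± 1.63 against 6.53% ± 0.899 (SD, n = 5 each; exact permutation p = 0.0238, adjusted p = 0.0905). Tbx3 had 6 of 8 higher, with 9.87% ± 1.87 against 8.22% ± 0.889 (SD, n = 5 each; exact permutation p = 0.103). Ubtf, which encodes a factor of ribosomal RNA transcription, had 6 of 8 higher, with 2.77% ± 0.557 against 1.74% ± 0.329 (SD, n = 5 each; exact permutation p = 0.0159, adjusted p = 0.0754). Regions nearest to annotated ribosomal RNA genes had 67 of 83 higher (80.7%; Fisher's exact test, p = 0.0518, adjusted over 4 classes p = 0.104). Of these, 5_8S_rRNA had 55 of 63 higher and 5S_rRNA 12 of 20, the latter with a mean difference of −0.0439 points; the split between them was not tested. Their medians per animal overlapped, with 8.53% to 13.4% in paternal high-fat and 5.57% to 14.4% in paternal chow offspring. A q below 0.05 in the authors' deposited table was held by 4 of the 83 regions (Fisher's exact test, p = 0.0053, adjusted p = 0.0212). All 4 were intergenic, at 5557, 39767, 42374 and 398921 bases from the start site of the ribosomal RNA gene named. The 2 at 39767 and 42374 bases are named for the same copy, lie close together and are not independent. The class therefore rests on the nearest annotated gene, and these 4 regions are not shown to lie in ribosomal RNA genes. None of the 19 gene names passed after adjustment.

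The majority of higher regions was weighed first: of 100 splits of the 10 animals into 5 and 5, drawn from 126 with the real one included, 7 gave a majority as large as 71.0%, and the highest other was 76.01%, but the regions were selected on the real split and this says nothing about chance. Incomplete bisulfite conversion in the paternal high-fat libraries as the whole cause is argued against by the share of higher regions at intermediate level. It would add as many points or fewer there, yet 80.1% of regions were higher against 70.1% up to 5% methylation. The median difference was 5.21 points against 1.32 up to 5% methylation. Over animals, the mean level between 20% and 80% differed by 4.07 points and up to 5% by 0.780 points, a gap of 3.29 points (SE 0.824, n = 5 each) that was 2.84 to 3.78 with any 1 animal left out. These sizes decide little, because paternal high-fat animals also varied more at intermediate level (SD 1.90 against 0.549). Selection for a group difference favours larger differences where animals vary more, and the share too holds only within the selected regions. Above 80% methylation the values go with incomplete conversion, which has little to add there: 56.5% of 131 regions were higher (95% Clopper-Pearson interval 47.6% to 65.1%), with a median difference of 1.597 points, and the mean level differed by 0.716 points (SE 0.447, n = 5 each). A contribution of incomplete conversion at low and high levels therefore stays open. Up to 5% methylation the level of each group where it was the lower one differed by −0.0399 points (paternal high-fat minus paternal chow), but splitting regions by the difference itself makes this comparison decide nothing. Paternal diet, sire, litter, sex and cell makeup stay open and were not tested.

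The second pattern is the 76 regions of the authors' deposited table beside 0 by limma. The real split gave 0 limma calls and the highest other split 1; a count of 0 is reached by all 100 splits whatever the data, so this says nothing about chance. The real split had 1875 regions at unadjusted p below 0.05 against 988 in the highest other, and 1 of 100 splits reached it, but the regions were selected on the real split and this says nothing about chance. The deposited Mann-Whitney p was 8.28e-14 at Adamts2 and 1.54e-12 at Galp. With 1 value per animal, a two-sided Mann-Whitney test of 5 against 5 cannot go below 0.00794. The deposited Mann-Whitney test therefore counted more than 1 value per animal. At named regions the q followed the Kolmogorov-Smirnov p instead (1.52e-12 at Adamts2), for which no such limit was worked out. A candidate explanation of the disagreement is that each CpG of an animal entered the deposited p as a separate value. Regions with a deposited q below 0.05 held 6.71 more CpGs than regions with a matched limma statistic (permutation p = 0.0001, the smallest that 10000 draws can give), in the direction this needs; metilene was not rerun.

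X-linked regions near start sites lay at intermediate methylation in all 10 animals, with medians of 16.3% to 25.3%, while autosomal medians near start sites were 1.11% to 3.07%. Hypothesis: the animals may be female, with methylation of the inactive X, since the labels do not state the sex of the offspring used. The lowest X median was 5.30 times the highest autosomal median, just above a limit of 5 that was set after rough values had been seen, and the regions were selected for a group difference, so this is weak evidence. A second hypothesis was that columns with the same leading number share a litter or sire. Of the 10 pairs in each group, the pair 22HFB and 22HFR ranked 10 in the correlation of deviations from the group mean and the pair 6HFBB and 6HFB ranked 2, which decides nothing.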
